A study of Homo sapiens with 199 samples.

How the data were processed

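RNA was sequenced from the tubulointerstitial compartment of kidney biopsies of adults with nephrotic syndrome, in 199 libraries. Per the labels, RNA was extracted with a Qiagen AllPrep micro kit, and cDNA was made from polyadenylated RNA with the Takara SMART-Seq v4 ultra low input kit and oligo(dT) primers. That kit adds no molecular identifiers, so reads copied from 1 molecule are counted separately, and counting error is a lower bound on technical error. Per the submitters' processing notes, reads were checked with FastQC 0.11.5, trimmed with cutadapt 1.14, aligned with STAR 2.5.2 and assigned to genes with HTSeq, whose version was not stated. The genome build and annotation were not given in the sources used here. The deposited table held 1 raw read count per gene symbol and library, and every value was a whole number. By symbol, 18906 of 19238 entries were found in the GENCODE 29 annotation of GRCh38, from which the gene positions were taken, and 2 symbols were written as dates. In all, 1933 genes were at 0 in every library. XIST, TSIX and 47 genes of the Y chromosome were left out of all tests.

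Groups were taken from the diagnosis in the labels, with 70 FSGS, 59 MN, 32 MCD and 37 Other NS libraries. The library of unspecified diagnosis was left out of the comparisons. Libraries are numbered within their group in the order in which they were listed. The labels gave no clinical data, batch or treatment, so none could be adjusted for. The closest pair of libraries had a correlation of log2 CPM of 0.9746 and a chi-square of 112.4 per gene between them, and no library was treated as a repeat of another.

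Genes were kept by filterByExpr (minimum count 10), which left 14340. Counts were scaled by the trimmed mean of M-values (TMM) and fitted with all 198 libraries in a quasi-likelihood negative binomial model in edgeR 4.0.16 (R 4.3.3). All 6 pairs of groups and the difference across the 4 groups were tested, two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05. SE of a log2 fold change comes from that model. A total of 31 gene lists covered nephron segments, glomerular, vascular, stromal and immune cells, injury, matrix, stress, mitochondrial and metabolic programmes and genes tied to MN or to podocyte disease. A list's score in a library was the mean log2 CPM of its tested members (prior count 2). Scores were compared by two-sided permutation tests with 1e+05 resamples, adjusted over all lists and pairs, with SE from the spread of libraries and 95% intervals from it. Members were also adjusted over the list alone. That adjustment covers only the list's own genes and uses the same libraries as its score, so those counts are not separate evidence. The camera test of limma 3.58.1, which compares a list with the other genes, was run with a correlation between genes estimated from the data. Its p-values are those given below as with an estimated correlation. They answer another question than the permutation test, which asks whether the score differs between groups. The share of each score's variance explained by diagnosis, 8 correlations between scores and the first principal components were tested by permutation too.

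The lists, the tests and the rule for naming genes were chosen before the data were examined. The rule took, in each pair, genes with adjusted p under 0.05 and a mean of at least 5 CPM in the higher group, and named the 10 with the largest positive and the 10 with the largest negative log2 fold change. To these came the 2 members with the smallest adjusted p of each list that passed, and the markers HAVCR1, LCN2, EGF, UMOD, VCAM1, CCL2, TIMP1, C3, COL1A1, PLA2R1, APOL1, LRP2, FKBP5 and IFI44L in every pair. Segments of immunoglobulin and T cell receptor genes, pseudogenes and read-through names were counted but not named. The result of 1 further gene is not reported here.

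The alternatives planned beforehand were size factors by relative log expression (RLE), no low-count filter, a stricter filter (at least 1 CPM in most libraries), DESeq2 1.42.0, limma-voom, a rank test (Wilcoxon, or Kruskal-Wallis across the groups), a fit of the compared groups alone, and covariates for library size, the podocyte score or the nephron segment. The nephron segment covariate was the proximal tubule score minus the mean of the thick ascending limb and principal cell scores. Others left out the 20 libraries with the fewest counts, and for lists used the median over genes, z-scores, camera or a prior count of 0.5. Added after seeing the data were fits without the 7 libraries above 100 CPM of 25 skeletal muscle genes, without the 5 libraries least similar to the others, and without single libraries.

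The gene test was tested on simulated data that kept the libraries' sizes and each gene's spread, with 200 changed genes, 50 at each fold. Genes were drawn independently of each other, so the correlation between genes in the real libraries was absent. The shares of false calls below hold for such data only. With shuffled labels of the real libraries, FSGS against MCD gave up to 1931 genes (median 2). For FSGS against MCD, run on 14291 genes, 74%, 92%, 90% and 98% of the genes changed 1.5, 2, 3 and 4-fold were recovered, and 4.32% of calls were false. For MN against MCD (14282 genes) recovery was 58%, 84%, 94% and 100%, with 4.55% false. FSGS against MN (14310 genes) gave 80%, 92%, 100% and 98%, with 3.65% false. Other NS against MCD (14293 genes) gave 60%, 82%, 90% and 98%, with 2.37% false, Other NS against FSGS (14299 genes) 68%, 82%, 98% and 100%, with 2.25% false, and Other NS against MN (14280 genes) 56%, 84%, 92% and 98%, with 2.37% false. The list test for FSGS against MCD was run on 31 lists with shuffled libraries, adjusted over that pair alone. Of 3 lists shifted by 0.5 log2, 0 passed (all 3 had an unadjusted p under 0.05). Of 3 other lists shifted by 1, 3 passed. The spread of scores differs between lists and the real test was adjusted over all pairs, so these shifts set no limit of detection. Of 25 lists without a shift 0 passed.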

Results

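Gene expression was measured as RNA sequencing read counts in the tubulointerstitial compartment, the tubules and surrounding tissue outside the glomeruli, of kidney biopsies from adults with nephrotic syndrome. The count table held 19238 gene symbols per library. By their labels, 70 libraries came from focal segmental glomerulosclerosis (FSGS), a pattern of segmental glomerular scarring. Another 59 came from membranous nephropathy (MN), in which antibodies deposit along the glomerular basement membrane, and 32 from minimal change disease (MCD), in which glomeruli look nearly normal by light microscopy. Other nephrotic syndrome (Other NS) accounted for 37, and the diagnoses within that group were not given. A single library carried an unspecified label and entered no comparison. The labels named no tissue from people without nephrotic syndrome, and no batch or treatment. Library totals ran from 17.6 to 48.7 M counts (median 28.4 M, where M is 1e6 counts), with medians of 28.3 M in FSGS, 28.7 M in MN, 28.1 M in MCD and 28.1 M in Other NS. Library size did not differ detectably between the groups (permutation p = 0.669), nor did the share of counts on mitochondrial genes (p = 0.314). The most abundant gene of a library took 5.52% ± 2.21 (SD, n = 70) of the counts in FSGS, 6.46% ± 2.02 (n = 59) in MN, 6.62% ± 1.82 (n = 32) in MCD and 5.23% ± 1.95 (n = 37) in Other NS, which did differ (permutation p = 0.00273). The TMM scaling factor (permutation p = 0.0237) and a library's median correlation with the others (p = 0.033) also differed between the groups, and of the 5 libraries least similar to the others 4 were FSGS and 1 was MN. Each p-value measures the spread between libraries, and the labels did not say whether any person gave more than 1 library.

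Across the 4 groups, lymphocyte and macrophage transcripts varied most with the diagnosis. The mean log2 CPM (counts scaled to 1e6 per library) of T and natural killer (NK) cell genes was 1.17 ± 1.60 (SD, n = 70) in FSGS, 0.31 ± 1.13 (n = 59) in MN, -0.27 ± 1.2 (n = 32) in MCD and 1.32 ± 1.37 (n = 37) in Other NS. Diagnosis accounted for 16.1% of the variance of that score between libraries, for 13.2% with macrophage and monocyte genes, 11.2% with B and plasma cell genes and 10.8% with MHC class II antigen presentation genes. Fatty acid oxidation (9.64%), tubular injury (9.57%), extracellular matrix (9.08%), targets of tumour necrosis factor (TNF) and NF-kB (8.74%), complement (7.32%) and intercalated cells of the collecting duct (5.98%) also passed, with adjusted p from 0.000155 to 0.0216 over 31 lists. Podocyte genes, which mark glomerular cells, had 0.414% of their variance explained (adjusted p = 0.905), and proximal tubule genes 3.81% (adjusted p = 0.125). By the edgeR test of all groups at once, 1198 of 14340 genes differed. That number was 665 with limma-voom, 651 with the nephron segment covariate, 676 without the 20 smallest libraries and 1934 with no low-count filter. The first principal component held 19.2% of the variance, and diagnosis accounted for 10.9% of it (adjusted p = 3e-04). Its Pearson r was -0.911 with the tubular injury score, -0.903 with macrophages, -0.889 with T and NK cells and -0.872 with extracellular matrix. With fatty acid oxidation r was 0.891 and with the proximal tubule 0.75, against 0.015 with podocytes. Differences in these immune, matrix, injury and metabolic lists are therefore not separate results, since the scores largely moved together.

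**Figure D1:**
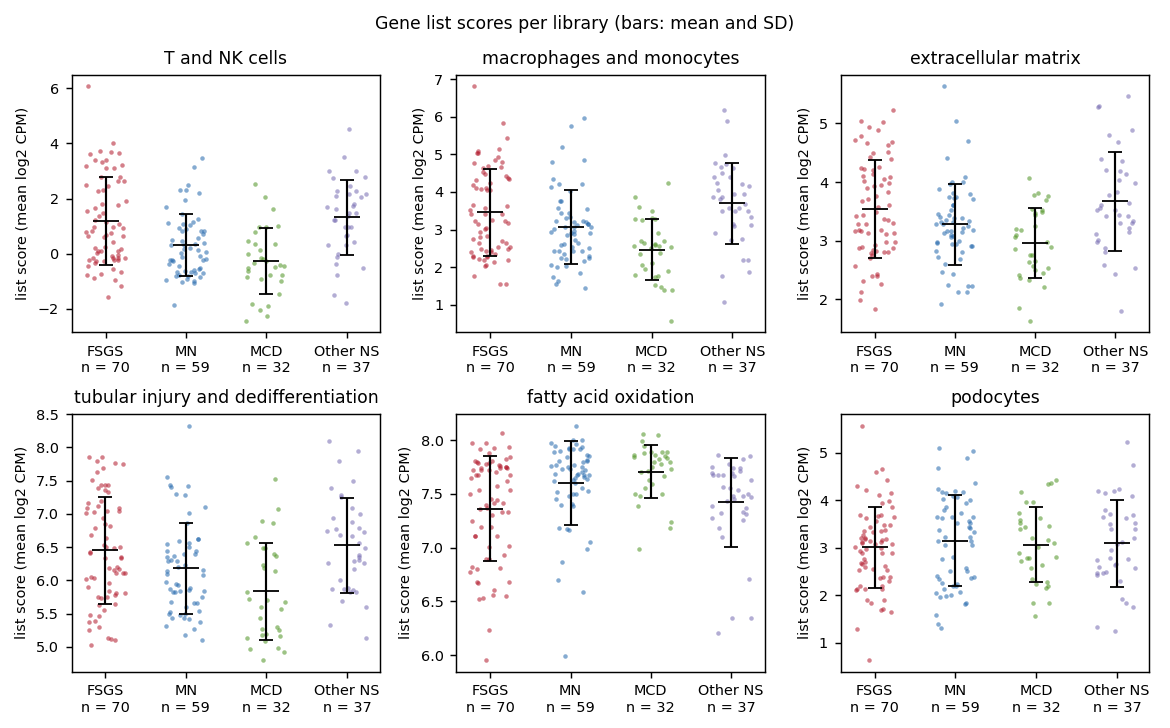
Scores of 6 gene lists (mean log2 CPM over the list) in each library, by diagnosis; points are libraries and the bars give the mean and SD. T and NK cell scores averaged 1.17 in FSGS and 1.32 in Other NS against -0.27 in MCD, with wide overlap of the libraries.

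The comparison of FSGS with MCD addressed which transcripts outside the glomerulus differ between a scarring lesion and one with little structural change. Transcripts of T and NK cells, B lineage cells and macrophages were higher in FSGS (n = 70) than in MCD (n = 32), with list scores 2.71-fold, 2.07-fold and 1.98-fold those of MCD. None of these 3 lists passed camera with an estimated correlation (adjusted p = 0.245, 0.369 and 0.245). Here and below, that test asks whether a list differs more than the other genes, not whether its score differs between groups. CD3E, a subunit of the T cell receptor complex (chromosome 11, 118304545 to 118316175), was 5.15-fold higher (log2 fold change 2.37, SE 0.42, adjusted p = 0.000107), at 7.59 ± 19.01 CPM (SD) against 1.47 ± 1.959. MZB1, a protein of antibody-secreting cells (chromosome 5, 139387480 to 139390081), was 8.13-fold higher (log2 3.02, SE 0.54, adjusted p = 0.000107). LYZ, the lysozyme of macrophages and monocytes (chromosome 12, 69348341 to 69354234), stood at 32.9 ± 89.9 CPM against 5.70 ± 7.62, a 5.76-fold difference (adjusted p = 0.000191). Without FSGS library 24, which held their highest levels, CD3E was 3.65-fold and LYZ 4.01-fold higher (edgeR adjusted p = 0.000824 and 0.00182). Of 14340 genes tested, 1185 were higher and 349 lower in FSGS, and 557 of the higher and 6 of the lower ones differed by over 2-fold.

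All 16 measured T and NK cell genes rose in FSGS, both over all genes and adjusted over the list alone. Their score was 1.44 log2 higher (SE 0.29, 95% interval 0.88 to 2, adjusted p = 0.00062, or adjusted p = 0.245 with an estimated correlation), and 61 of 70 FSGS libraries lay above the MCD median. All 18 macrophage and monocyte genes rose as well, LAPTM5, a lysosomal protein of leukocytes, by 1.55 log2 (SE 0.28), and their score was 0.99 higher (SE 0.20, adjusted p = 0.00186, or adjusted p = 0.245 with an estimated correlation), above the MCD median in 48 of 70 libraries. Among 10 B and plasma cell genes 8 rose (9 adjusted over the list alone). CD79A, part of the B cell receptor (chromosome 19, 41877120 to 41881372), was 11.2-fold higher at 5.65 CPM against 0.498, and the score 1.05 higher (SE 0.24, adjusted p = 0.00779, or adjusted p = 0.369 with an estimated correlation) in 52 of 70 libraries. MS4A1, which encodes the B cell antigen CD20, was 12.5-fold higher but missed the threshold with limma-voom (adjusted p = 0.0529) and by rank (0.0705). Without FSGS library 24, which held their highest levels, CD79A was 7.97-fold and MS4A1 8.46-fold higher. In the MHC class II list 6 of 12 genes rose (9 adjusted over the list alone), HLA-DPA1 1.77-fold, with a score 0.66 higher (adjusted p = 0.00635, or 0.369 with an estimated correlation) in 54 of 70 libraries. For TNF and NF-kB targets 9 of 20 rose (14 adjusted over the list alone), among them the neutrophil chemokine CXCL6 (log2 2.26) and LTB, the lymphotoxin beta chain (log2 1.61), with a score 0.74 higher (adjusted p = 0.00635, or 0.369 with an estimated correlation) in 59 of 70 libraries.

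Matrix and injury genes of the tubule also rose in FSGS. In the extracellular matrix list 20 of 33 genes rose (27 adjusted over the list alone), such as LUM, a collagen-binding proteoglycan, at 157 ± 168 CPM against 68.6 ± 44.01, and LOXL1, which helps cross-link elastin (1.98-fold). That score was 0.58 higher (SE 0.15, adjusted p = 0.00635, or adjusted p = 0.369 with an estimated correlation) in 50 of 70 libraries. COL1A1, a chain of type I collagen, had a log2 difference of 0.91 that did not pass (adjusted p = 0.068, but 0.0298 with DESeq2). Of 28 tubular injury genes 12 rose (20 adjusted over the list alone), PROM1 2.34-fold and the annexin ANXA3 1.74-fold, and the score was 0.62 higher (SE 0.16, adjusted p = 0.00449, or adjusted p = 0.369 with an estimated correlation) in 57 of 70 libraries. LCN2, a secreted marker of tubular injury (chromosome 9, 128149071 to 128153455), was 4.38-fold higher (adjusted p = 0.00377), and LCN2, FSGS vs MCD, had an adjusted p = 0.0655 with the nephron segment covariate. HAVCR1, a marker of injured proximal tubule, had a log2 difference of 0.84 (adjusted p = 0.0882) and passed with limma-voom (0.043) and by rank (0.0306). In the complement list 9 of 19 genes rose (9 rose and 1 fell adjusted over the list alone), including C3AR1, the C3a receptor (2.49-fold), and the protease C1S (2.20-fold). The complement score was 0.37 higher (SE 0.12, adjusted p = 0.0304, or adjusted p = 0.551 with an estimated correlation) in 53 of 70 libraries, and it missed the threshold with the median over the list (0.33, adjusted p = 0.11), with z-scores (0.29, adjusted p = 0.08) and without the 20 smallest libraries (0.32, adjusted p = 0.134). C3, the central complement protein (chromosome 19, 6677704 to 6730562), rose 2.38-fold (adjusted p = 0.0131) but not with limma-voom (0.0523) or without the 20 smallest libraries (0.0595).

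Fatty acid oxidation genes fell in FSGS, 10 of 25 over all genes and 16 adjusted over the list alone. The score was -0.35 log2 (SE 0.07, adjusted p = 0.00449, or adjusted p = 0.245 with an estimated correlation), below the MCD median in 57 of 70 libraries, and HADHB, a subunit of the trifunctional protein of beta-oxidation, was at 0.809 of its MCD level. Intercalated cell genes had a score difference of -0.43 (adjusted p = 0.0546), with 3 of 14 lower (7 adjusted over the list alone), and proximal tubule genes one of -0.49 (adjusted p = 0.113). Neither podocytes (-0.06, adjusted p = 0.861) nor endothelium (0.16, adjusted p = 0.349), fibroblasts, pericytes and smooth muscle (0.35, adjusted p = 0.111) or red blood cells (0.50, adjusted p = 0.2) passed. Differences for other segments were -0.19 for the thick ascending limb (adjusted p = 0.376), -0.37 for the distal convoluted and connecting tubule (0.112) and -0.06 for principal cells (0.841). Stress and metabolic lists that did not pass were type I interferon response (0.29, adjusted p = 0.206), immediate early response (0.33, 0.112), heat shock (-0.10, 0.307), unfolded protein response (0.01, 0.931), hypoxia (-0.01, 0.861), metallothioneins (-0.17, 0.698), cell cycle (0.15, 0.766), cholesterol synthesis (-0.04, 0.729), nuclear oxidative phosphorylation (-0.16, 0.0972), mitochondrially encoded mRNAs (-0.21, 0.56) and glucocorticoid-induced genes (-0.0036, 0.976). Lists of membranous nephropathy antigens (0.04, adjusted p = 0.841) and monogenic podocyte disease genes (0.02, adjusted p = 0.892) did not pass either. For podocytes and for mitochondrially encoded mRNAs the median gene had the opposite sign, 0.05 and 0.03.

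Outside the lists, SFRP2, a secreted Wnt modulator of fibroblasts (chromosome 4, 153780592 to 153789120), rose 6.52-fold (log2 2.71, SE 0.61, adjusted p = 0.000921). FGG, the fibrinogen gamma chain, rose 5.92-fold and the mast cell tryptase TPSAB1 5.83-fold, and CCL19, a chemokine that attracts lymphocytes, 6.68-fold (adjusted p = 0.0552 with limma-voom). Transcripts that fell were the lysosomal protease CTSV (log2 -0.92), the carboxypeptidase N subunit CPN2 (-0.82), SHBG, the sex hormone-binding globulin (-0.86), and the tissue kallikrein KLK1 (-1.50). SHBG had an adjusted p = 0.0749 and KLK1 an adjusted p = 0.136 without the 20 smallest libraries. Some passing genes missed the threshold without the library that held their highest level. CCL18 and CHIT1, products of activated macrophages, went from log2 2.99 to 1.85 (adjusted p = 0.0837) and from 2.64 to 1.53 (0.126) without FSGS library 61, and ANGPTL4 from -1.56 to -0.89 (0.186) without MCD library 17. Smaller shifts ended the calls of the monocyte chemokine CCL2 (0.94 to 0.77, adjusted p = 0.0503 without FSGS library 26), oxytocin (OXT, -0.92 to -0.65, 0.126 without MCD library 4), the anion exchanger SLC26A4 (-0.83 to -0.69, 0.0994 without MCD library 3), PLAAT5 (-0.82 to -0.67, 0.113 without MCD library 28) and antithrombin (SERPINC1, -0.77 to -0.70, 0.0799 without MCD library 8). APOL1, in which some variants raise the risk of kidney disease (chromosome 22, 36253010 to 36267530), was 1.58-fold higher (adjusted p = 0.00578, but 0.0665 by rank). EGF, made in the distal nephron (log2 -0.58, adjusted p = 0.14, but 0.033 with limma-voom), UMOD (-0.34, 0.509), VCAM1 (0.37, 0.225), PLA2R1 (-0.01, 0.977), LRP2 (-0.25, 0.287), FKBP5 (-0.52, 0.158) and IFI44L (0.72, 0.19) did not pass. TIMP1, an inhibitor of matrix proteases (chromosome X, 47582313 to 47586789), was listed at 0 in every library, as were 32 members of the fixed lists in total, among them CD68, CCL5 and CXCL10. The number of genes that differed was 844 by rank and 883 with the nephron segment covariate, of which 761 and 873 were among the 1534.

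**Figure D2:**
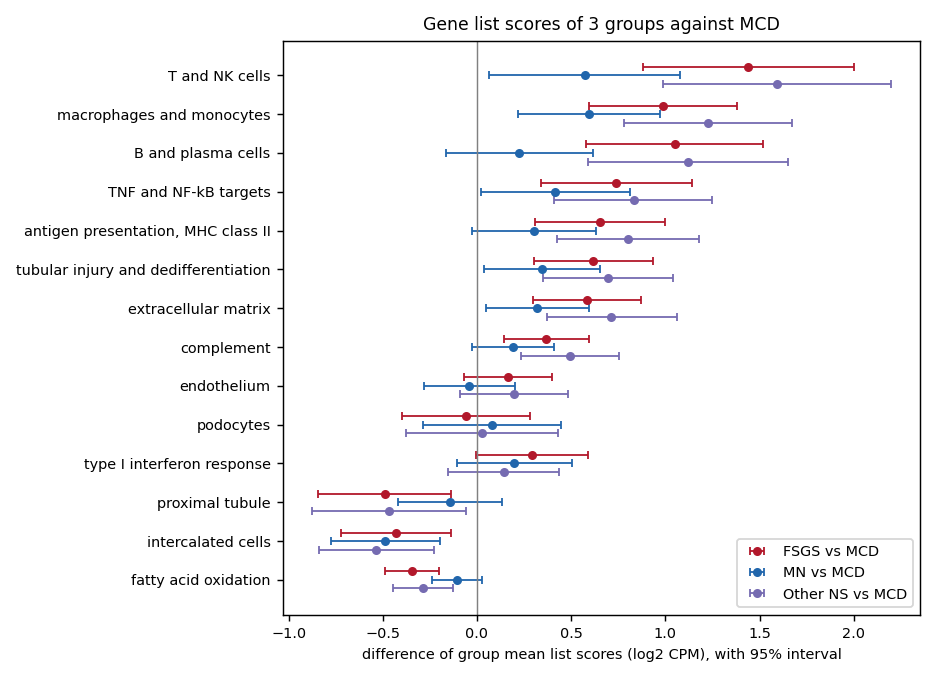
Difference of the mean list score (log2) from MCD for FSGS, MN and Other NS, for 14 gene lists; points are the differences and bars their 95% intervals. The T and NK cell difference was 1.44 for FSGS and 1.59 for Other NS, and fatty acid oxidation lay at -0.35 and -0.29.

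MN was set against MCD to ask what the tubulointerstitium of an antibody-mediated glomerular disease shows beside minimal change. Few genes separated MN (n = 59) from MCD (n = 32): 9 were higher and 5 lower, with 1608 of 14340 at an unadjusted p under 0.05. ECM1, a secreted matrix protein (chromosome 1 from 150508062), was 2.23-fold higher (log2 1.16, SE 0.26, adjusted p = 0.0311), at 6.30 ± 5.82 CPM (SD) against 2.83 ± 2.11. PHLDA3, a p53 target, was 1.81-fold higher (adjusted p = 0.0311) and RHEX, a regulator of erythroid cells, 1.87-fold (adjusted p = 0.0375). VPS37D (log2 0.66), the receptor ADGRF1 (-0.59) and the nuclear protein CEBPZ (-0.22) passed too.

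Intercalated cell genes, which mark the acid-base regulating cells of the collecting duct, were lower in MN as a list (-0.49, SE 0.15, adjusted p = 0.0142, or adjusted p = 0.245 with an estimated correlation) in 44 of 59 libraries. Of 14 members 0 passed over all genes and 11 fell adjusted over the list alone, which is not evidence separate from the list score. The proton pump subunit ATP6V0A4 had a log2 difference of -0.49 (adjusted p = 0.0936) and the ammonia channel RHCG (chromosome 15, 89471398 to 89496613) of -0.77 (adjusted p = 0.106). Macrophage and monocyte genes scored 0.60 higher (SE 0.19, adjusted p = 0.0275, or adjusted p = 0.369 with an estimated correlation) in 39 of 59 libraries, with 0 of 18 members passing over all genes and 15 higher adjusted over the list alone. CD163, a scavenger receptor of macrophages, had a log2 difference of 1.144 (adjusted p = 0.15) and the complement subunit C1QA of 0.85 (adjusted p = 0.172). Without the 20 smallest libraries neither list passed (0.59, adjusted p = 0.0725 for macrophages and -0.38, adjusted p = 0.1 for intercalated cells), and the intercalated list also missed with the median over its genes (-0.36, adjusted p = 0.11). Other lists lay on the same sides without passing. T and NK cells were at 0.57 with 16 of 16 genes positive (adjusted p = 0.111), tubular injury at 0.35 (0.111), extracellular matrix at 0.32 (0.115) and TNF and NF-kB targets at 0.42 (0.141). The distal convoluted and connecting tubule was at -0.31 (0.137). LCN2 was at 12.1 ± 45.3 CPM against 3.68 ± 6.07 (adjusted p = 0.173), and PLA2R1, the main target antigen of MN (chromosome 2 from 159932006), at 26.6 ± 20.9 against 20.5 ± 13.8 (adjusted p = 0.516). Known MN antigens as a list differed by 0.09 (adjusted p = 0.562). The genes named as past the threshold for MN missed it once their highest library was left out, with folds close to those before. ECM1 was at 2.07-fold (adjusted p = 0.0586) without MN library 23, and RHEX at 1.79 (0.0879) and PHLDA3 at 1.75 (0.0537) without MN library 14. VPS37D was at 1.53 (0.0923, against 1.58 with MN library 42), ADGRF1 at 0.703 (0.107, against 0.664 with MCD library 14) and CEBPZ at 0.887 (0.12, against 0.861 with MCD library 4). The count of 14 was 0 with limma-voom, by rank and with the stricter filter, 1 with a library size covariate, 3 with these groups alone, 8 without the 7 libraries rich in muscle genes, 9 without the 20 smallest libraries, 54 with DESeq2 and 131 with no filter. Leaving out MCD library 8 gave 5 genes, and MCD library 24 gave 7.

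FSGS against MN compared both diagnoses directly. ABCG1, an exporter of cellular cholesterol (chromosome 21, 42199689 to 42297244), had 0.519 of its MN level in FSGS (log2 -0.95, SE 0.15, adjusted p = 1.22e-05), at 23.2 ± 14.9 CPM (SD, n = 70) against 44.8 ± 19.1 (n = 59). SREBF1, which encodes a transcription factor of lipid synthesis (chromosome 17, 17810399 to 17837002), fell by 0.61 (SE 0.14, adjusted p = 0.00589), and PHKA1, a phosphorylase kinase subunit, by 0.58 (SE 0.13, adjusted p = 0.00392). These 3 passed with every other tool too, ABCG1 by rank at adjusted p = 1.98e-06. Among the genes higher in FSGS, the chemokine CCL21 (chromosome 9, 34709005 to 34710124) was 4.43-fold higher (log2 2.15, SE 0.34, adjusted p = 1.37e-05), CCL19 (chromosome 9, 34689567 to 34691277) 5.34-fold and CD3E 3.27-fold (both adjusted p = 0.000424), and these 3 missed by rank (adjusted p = 0.103, 0.126 and 0.134) and with limma-voom (0.106, 0.143 and 0.115).

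Altogether 371 genes were higher and 35 lower in FSGS than in MN by edgeR. In the T and NK cell list 15 of 16 rose (16 adjusted over the list alone), including CD3D (log2 1.68), the kinase LCK (1.55) and NKG7 (1.31), a granule protein of cytotoxic cells. The list score was 0.87 higher (SE 0.24, adjusted p = 0.00635, or adjusted p = 0.245 with an estimated correlation) in 45 of 70 libraries. Of 10 B and plasma cell genes 6 rose (7 adjusted over the list alone), MZB1 by 1.72 and the receptor FCRL5 by 2.23, with a score 0.82 higher (SE 0.24, adjusted p = 0.00871, or 0.245 with an estimated correlation) in 48 of 70 libraries. Fatty acid oxidation was -0.24 (SE 0.08, adjusted p = 0.0214, or 0.245 with an estimated correlation) and below the MN median in 44 of 70 libraries, beside a proximal tubule score of -0.35 (SE 0.18, adjusted p = 0.187). Within it 2 of 25 genes fell (6 adjusted over the list alone), CPT2 by 0.31 and the carnitine carrier SLC25A20 by 0.25. Without the 20 smallest libraries none of these 3 lists passed (T and NK cells, FSGS vs MN, adjusted p = 0.0556; B and plasma cells, FSGS vs MN, 0.0853; fatty acid oxidation, FSGS vs MN, 0.0941). SCD, an enzyme that desaturates fatty acids, fell by 0.50 (adjusted p = 0.0381, or 0.057 without MN library 7), the acyl-CoA thioesterase ACOT12 by 0.70, the kinase MAPK12 by 0.50 and F13A1, a clotting factor subunit made by macrophages, by 0.68. ECEL1 (log2 2.11) and IL2RG, the common chain of several cytokine receptors (1.53), rose. Without FSGS library 24 CD79A went from 3.39-fold to 2.44-fold (adjusted p = 0.126) and the homing receptor CCR7 from 3.16-fold to 2.25-fold (0.135). HFM1 went from 0.630 to 0.773 of its MN level (adjusted p = 0.249) without MN library 13. CREB3L3 (0.585 to 0.633, adjusted p = 0.107 without MN library 50) and SLC25A20 (0.839 to 0.853, 0.0809 without MN library 33) shifted less. No gene fixed beforehand as a marker passed by edgeR, the smallest adjusted p being 0.0974 for CCL2. LCN2 (log2 0.41, adjusted p = 0.614) passed with DESeq2 alone (0.00767).

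The upper genes of this comparison depended on the tool and on a few libraries. The count of 406 was 11 with limma-voom and 21 by rank, of which 11 and 19 were among the 406. With limma-voom 5 were higher and 6 lower in FSGS, and by rank 8 higher and 13 lower. The excess of higher genes thus held with neither, while DESeq2 kept it (534 higher and 53 lower). Of the genes named above CCL21, CCL19, ECEL1, CD3E, CD3D, LCK, IL2RG, NKG7, MZB1, FCRL5, CD79A, CCR7, F13A1, SCD, CPT2, SLC25A20, CREB3L3 and HFM1 missed with both, as MAPK12 did with limma-voom (adjusted p = 0.0868). ACOT12 missed without the 20 smallest libraries (adjusted p = 0.0591 for ACOT12, FSGS vs MN). The number was 41 with the nephron segment covariate, 79 without the 20 smallest libraries, 106 without the 5 libraries least similar to the others, 727 with no filter, 117 without FSGS library 24, 235 without FSGS library 3 and 698 without MN library 14.

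**Figure D3:**
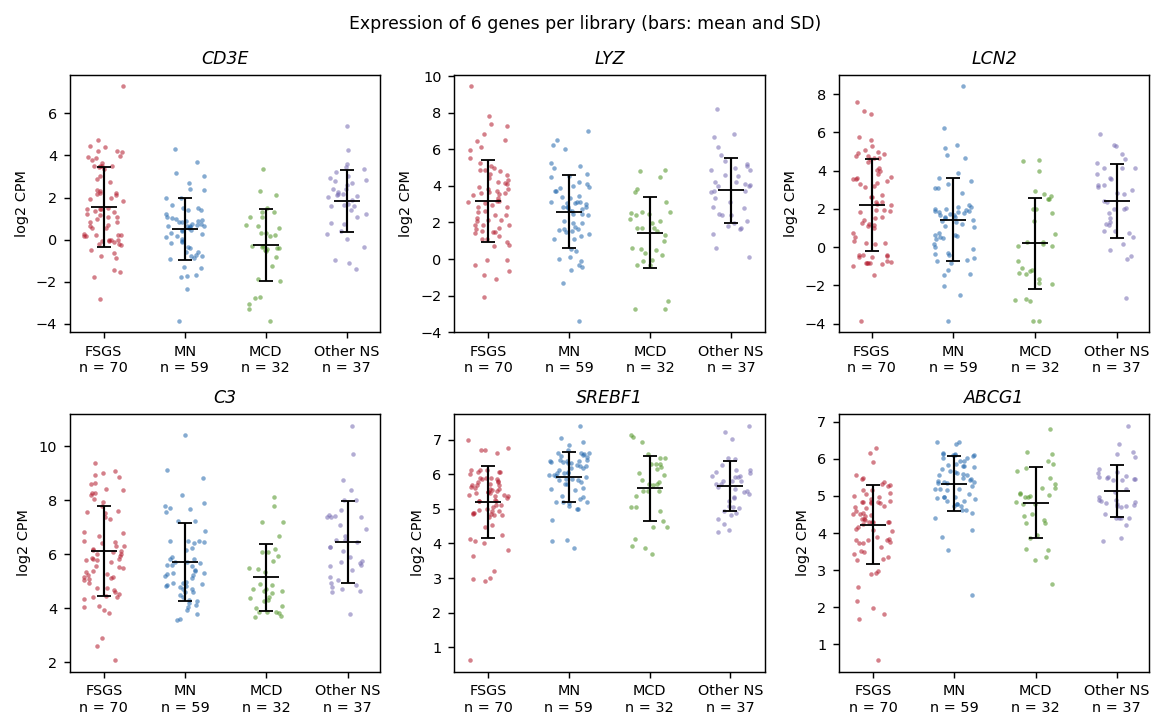
Expression (log2 CPM) of CD3E, LYZ, LCN2, C3, SREBF1 and ABCG1 in each library, by diagnosis; points are libraries and the bars give the mean and SD. ABCG1 averaged 23.2 CPM in FSGS and 44.8 in MN, and SREBF1 fell by 0.61 on the log2 scale in FSGS relative to MN.

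Other NS against MCD had the second largest number of differing genes, 732 higher and 155 lower. SFRP2 was 13.3-fold higher (log2 3.74, SE 0.67, adjusted p = 0.000152), at 12.6 ± 44.3 CPM (SD, n = 37) against 0.942 ± 1.63 (n = 32), and 5.72-fold higher without Other NS library 17. MZB1 was 9.29-fold higher (adjusted p = 0.000152) and FGB, the fibrinogen beta chain (chromosome 4 from 154562956), 6.95-fold (adjusted p = 0.00246). LAPTM5 rose 2.97-fold and the complement subunit C1QC 3.15-fold. RHCG fell by 0.88 (SE 0.24, adjusted p = 0.0105), at 178 ± 103 CPM against 326 ± 218.

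T and NK cell genes scored 1.59 log2 higher (SE 0.31, adjusted p = 0.00062, or 0.245 with an estimated correlation) in 33 of 37 libraries, and 15 of 16 rose (16 adjusted over the list alone), such as perforin (PRF1, log2 1.45) and CD6 (1.95). Macrophage and monocyte genes scored 1.23 higher (SE 0.23, adjusted p = 0.00062, or 0.245 with an estimated correlation) in 32 of 37 libraries, with 17 of 18 higher (18 adjusted over the list alone). MHC class II genes, 7 of 12 higher (10 adjusted over the list alone), scored 0.80 higher (adjusted p = 0.00372, or 0.245 with an estimated correlation) in 32 of 37 libraries, and HLA-DQA1 rose 2.76-fold. In the B and plasma cell list 4 of 10 rose (8 adjusted over the list alone), CD79A by 2.85, with a score 1.12 higher (adjusted p = 0.00393, or adjusted p = 0.373 with an estimated correlation). Extracellular matrix scored 0.71 higher (adjusted p = 0.00393, or adjusted p = 0.301 with an estimated correlation) in 31 of 37 libraries, with 20 of 33 higher (24 adjusted over the list alone), the gelatinase MMP2 by 1.19 and LOXL1 by 1.12. The injury list scored 0.69 higher (adjusted p = 0.00393, or adjusted p = 0.304 with an estimated correlation) in 33 of 37 libraries, with 8 of 28 higher (13 adjusted over the list alone), PROM1 by 1.41 and ANXA1 by 1.10. TNF and NF-kB targets scored 0.83 higher (adjusted p = 0.00449, or adjusted p = 0.33 with an estimated correlation) in 33 of 37 libraries, with 5 of 20 higher (9 adjusted over the list alone), TNFRSF1B, a TNF receptor, by 1.13.

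Complement genes scored 0.49 higher (SE 0.13, adjusted p = 0.00615, or adjusted p = 0.48 with an estimated correlation) in 31 of 37 libraries, with 6 of 19 higher (9 adjusted over the list alone), CFD, the protease of the alternative pathway, 3.51-fold and C3AR1 2.75-fold. Without the 20 smallest libraries it missed (complement, Other NS vs MCD, adjusted p = 0.0518). C3 rose 3.17-fold (adjusted p = 0.00347, or 0.124 without the 20 smallest libraries). Fatty acid oxidation was at -0.29 (SE 0.08, adjusted p = 0.00672, or adjusted p = 0.369 with an estimated correlation), below the MCD median in 34 of 37 libraries, beside a proximal tubule score of -0.47 (SE 0.21, adjusted p = 0.111). With the median over the list it missed (fatty acid oxidation, Other NS vs MCD, adjusted p = 0.0978). In it 3 of 25 genes fell (7 adjusted over the list alone), CPT1A, which brings fatty acids into mitochondria, by 0.45. Intercalated cell genes were at -0.53 (SE 0.16, adjusted p = 0.00753, or adjusted p = 0.33 with an estimated correlation), below the MCD median in 28 of 37 libraries, and 4 of 14 fell (10 adjusted over the list alone), the proton pump subunit ATP6V1B1 by 0.67 and the anion exchanger SLC4A1 by 0.84. Podocyte genes and the other lists did not pass. ATP6V1B1 missed by rank (adjusted p = 0.0663). SHBG fell by 0.98, and it and SLC4A1 missed without the 20 smallest libraries (SHBG, Other NS vs MCD, adjusted p = 0.075; SLC4A1, Other NS vs MCD, adjusted p = 0.0612). APOL1 rose 1.65-fold (adjusted p = 0.0105, but 0.101 by rank and 0.0534 with limma-voom). The nuclear receptor NR4A1 fell by 1.24, the hormone STC1 by 1.02 and ANGPTL4, a lipase inhibitor, by 2.68, and all 3 missed by rank (adjusted p = 0.0941, 0.097 and 0.724). ANGPTL4 had 0.156 of its MCD level, and 0.251 without MCD library 17 (adjusted p = 0.01). LCN2 was at 10.9 ± 13.4 CPM against 3.68 ± 6.07 (log2 1.56, adjusted p = 0.0769 by edgeR) and passed by rank (0.0101), with limma-voom (0.0231) and with DESeq2 (0.021).

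Skeletal muscle transcripts topped the list of folds in this comparison. ACTA1, the actin of skeletal muscle, was 30.9-fold higher, the creatine kinase CKM 17.97-fold and the troponin TNNC2 13.4-fold. Other NS library 5 held the highest level of each, and without it the folds were 8.99 (adjusted p = 0.0544), 5.02 (adjusted p = 0.0949) and 4.45 (adjusted p = 0.00272). With all libraries ACTA1, CKM and TNNC2 each missed by rank, with limma-voom and with DESeq2. For TNNC2 the adjusted p was 0.424 by rank, 0.368 with limma-voom and 0.103 with DESeq2. Without the 7 libraries rich in muscle genes CKM was at -1.79 and TNNC2 at -0.25. Those 7 were picked by their level of muscle genes and included 3 of Other NS and 0 of MCD, so a fall was built in. C-reactive protein (CRP, 20.9-fold) rested on Other NS library 18, and without it was at log2 -1.26 (adjusted p = 0.396). The antimicrobial lectin REG3G (13.5-fold) was highest there too, and without that library was at log2 1.58, or 2.98-fold (adjusted p = 0.0915). With all libraries REG3G also passed by rank (adjusted p = 0.0119), with limma-voom (0.0331) and with DESeq2 (0.000484). CHIT1 went from 10.1-fold to 4.31-fold (adjusted p = 0.0787) without Other NS library 13, and the metallothionein MT1H from 0.544 to 0.742 of its MCD level (0.378) without MCD library 4. A smaller shift ended the call of COL1A1 (2.39-fold to 2.11-fold, adjusted p = 0.0673 without Other NS library 26). The same held for SERPINC1 (0.516 to 0.544, 0.0725 without MCD library 8), CTSV (0.533 to 0.582, 0.0849 without MCD library 1) and FRMD7 (0.548 to 0.582, 0.0715 without MCD library 24). The count of 887 was 511 without the 20 smallest libraries.

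**Figure D4:**
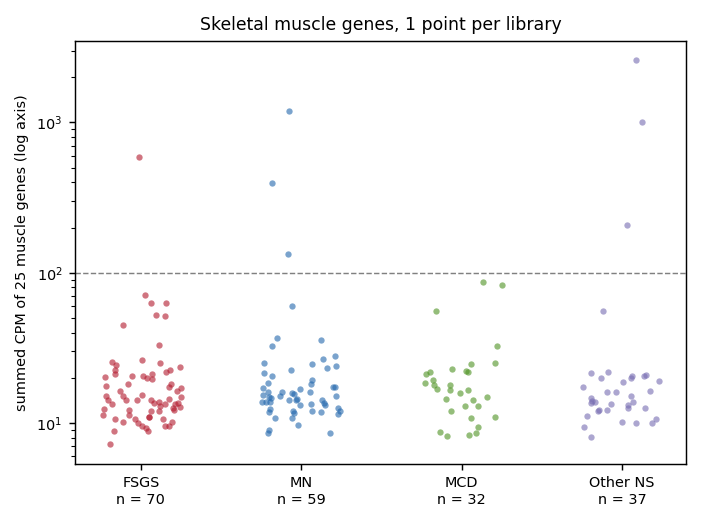
Summed CPM of 25 skeletal muscle genes in each library, by diagnosis, on a log axis; the dashed line marks 100 CPM. The 7 libraries above the line are 3 of Other NS, 3 of MN, 1 of FSGS and none of MCD, and the highest, Other NS library 5, reached 2606 CPM.

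Other NS and FSGS differed little, with 16 genes higher and 0 lower in Other NS by edgeR, 500 genes at an unadjusted p under 0.05, and 0 of 31 lists past the threshold (smallest adjusted p = 0.412). ABCG1 was 1.69-fold higher in Other NS (log2 0.76, SE 0.17, adjusted p = 0.0113), at 39.3 ± 21.4 CPM (SD, n = 37) against 23.2 ± 14.9 (n = 70). Its adjusted p was 0.0159 by limma-voom, 0.0669 by DESeq2 and 0.105 by rank. Without Other NS library 21 it was 1.6-fold higher (edgeR adjusted p = 0.0524). The remaining 6 named genes rested on single libraries. TNNC2 (log2 2.96), CKM (3.47), the muscle glycogen phosphorylase PYGM (1.61) and the muscle enolase ENO3 (1.03) had adjusted p of 0.879, 1, 1 and 1 without Other NS library 5, and CRP (2.996) and REG3G (2.24) had 0.346 and 1 without Other NS library 18. CRP then stood at -2.62. The camera test with an estimated correlation also called 0 lists. The count of 16 was 0 with DESeq2 and by rank, 1 with limma-voom, 2 without the 7 libraries rich in muscle genes, 3 with the stricter filter and with these groups alone, and 144 with no filter. It was 4 without Other NS library 5 and 8 without Other NS library 26.

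Set against MN, Other NS had 40 genes higher and 1 lower, with 1156 of 14340 at an unadjusted p under 0.05. CCL21 was 3.68-fold higher (log2 1.88, SE 0.38, adjusted p = 0.00195), at 59.6 ± 104 CPM (SD, n = 37) against 16.2 ± 20.4 (n = 59), and it passed by rank (adjusted p = 0.0206) but not with limma-voom (0.0712). CD4, the co-receptor of helper T cells, was 1.69-fold higher (adjusted p = 0.0125) and SLAMF7, a surface protein of plasma and NK cells, 3.26-fold (adjusted p = 0.0131). T and NK cell genes scored 1.02 higher (SE 0.27, adjusted p = 0.00393, or 0.245 with an estimated correlation) in 30 of 37 libraries, and 2 of 16 passed over all genes (15 adjusted over the list alone). B and plasma cell genes scored 0.89 higher (SE 0.27, adjusted p = 0.00705), macrophage and monocyte genes 0.63 (SE 0.22, adjusted p = 0.0275) and MHC class II genes 0.49 (SE 0.16, adjusted p = 0.0146), each at an adjusted p = 0.245 with an estimated correlation. Members past the threshold numbered 2 of 10 for B and plasma cells (4 adjusted over the list alone), 0 of 18 for macrophages (9) and 1 of 12 for MHC class II, HLA-DQA1 (10). Without the 20 smallest libraries T and NK cells passed and the others did not (B and plasma cells, Other NS vs MN, adjusted p = 0.0556; macrophages and monocytes, Other NS vs MN, 0.0941; antigen presentation, MHC class II, Other NS vs MN, 0.0556). Without the libraries rich in muscle genes macrophages and monocytes, Other NS vs MN, had an adjusted p = 0.0551.

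MZB1 (log2 1.91), DERL3 (1.64) and FCRL5 (2.24), genes of plasma cells, PLD4 (1.45), PRF1 (1.04), IL2RG (1.32) and CCL19 (2.02) were among those higher in Other NS than in MN, and STC1 fell by 0.96. Of 15 named genes that passed, 14 missed once their highest library was left out. Without Other NS library 18 REG3G went from 6.55-fold to 1.46-fold (adjusted p = 0.889), and without Other NS library 5 PYGM from 4.03-fold to 1.76-fold (0.478). For the others the fold moved less. Without Other NS library 1 it went from 4.06 to 2.80 for CCL19 (adjusted p = 0.466), from 3.68 to 2.78 for CCL21 (0.0735), from 2.74 to 2.25 for PLD4 (0.122) and from 2.49 to 2.10 for IL2RG (0.466). It also went, without that library, from 1.69 to 1.56 for CD4 (0.102), from 2.05 to 1.87 for PRF1 (0.212) and from 2.13 to 1.91 for HLA-DQA1 (0.338). Without Other NS library 17 it went from 3.77 to 3.09 for MZB1 (adjusted p = 0.124), from 3.26 to 2.83 for SLAMF7 (0.0906), from 3.11 to 2.30 for DERL3 (0.133) and from 4.72 to 3.71 for FCRL5 (0.186). Without MN library 18 it went from 0.513 to 0.539 for STC1 (0.0768). TNNC2 (log2 3.34) had 1.75 without Other NS library 5 (adjusted p = 0.0244). The count of 41 was 0 with limma-voom, 6 without the libraries rich in muscle genes, 7 without the 20 smallest libraries, 9 with the stricter filter, 21 with the nephron segment covariate, 25 by rank (6 of them among the 41) and with a library size covariate, 63 with these groups alone, 134 without the 5 least similar libraries and 194 with no filter. Leaving out Other NS library 1 gave 11, Other NS library 17 12, Other NS library 26 27 and MN library 14 86.

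Across the libraries of the 4 groups, matrix expression went with less proximal tubule expression and with more immune cell transcripts. Scores are relative to the counts of a library, so less tubule in a biopsy can raise other scores by itself. The relations below do not tell this apart from a change within cells. Proximal tubule scores fell as extracellular matrix scores rose (Pearson r = -0.52, Spearman rho = -0.687, permutation p = 1e-05 for each, the smallest the permutations can give), and r was -0.687 without the 2 libraries farthest from the median of the tubule score. Within the groups r was -0.416 in FSGS (-0.699 without the 2 farthest libraries), -0.699 in MN, -0.552 in MCD and -0.49 in Other NS. Tubular injury followed the proximal tubule in the opposite direction (r = -0.571, rho = -0.77, and -0.759 without the 2 farthest), with r of -0.431 in FSGS (-0.806 without the 2 farthest libraries), -0.784 in MN, -0.587 in MCD and -0.641 in Other NS. T and NK cell scores rose with matrix scores (r = 0.772, rho = 0.772), at 0.812 in FSGS, 0.743 in MN, 0.775 in Other NS and 0.46 in MCD, where it was 0.291 without the 2 farthest libraries. Complement and matrix had r = 0.807 (rho = 0.815), between 0.713 in MCD and 0.874 in Other NS. EGF expression fell with matrix (r = -0.573, rho = -0.519), but not detectably in MCD (-0.254, permutation p = 0.162). Nuclear oxidative phosphorylation rose with the proximal tubule score (r = 0.345, rho = 0.393, MCD 0.209 with p = 0.214), and immediate early and heat shock genes moved in opposite directions (r = -0.38, rho = -0.386, MCD -0.0428 with p = 0.817). Each of these 7 pooled relations had a permutation p of 1e-05 for r and for rho (adjusted p = 1.14e-05 over 8 pairs), and the eighth, podocytes with the proximal tubule, did not pass (r = 0.0578, rho = -0.0385, p = 0.418).

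**Figure D5:**
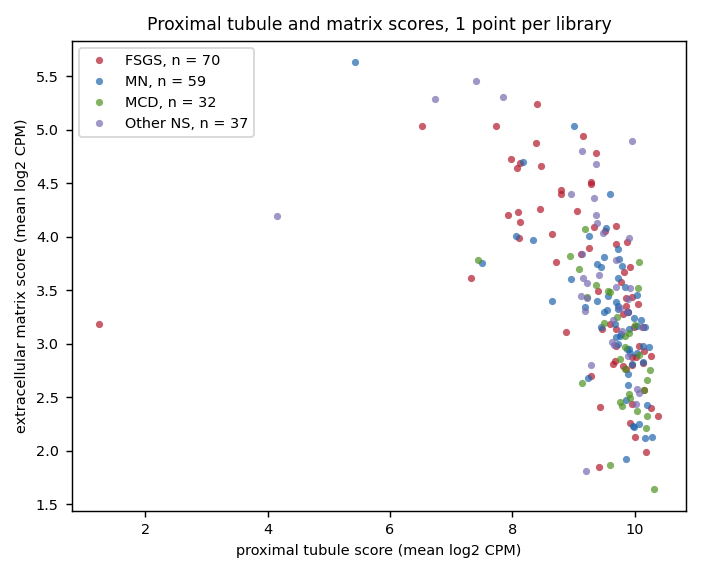
Proximal tubule score against extracellular matrix score (both mean log2 CPM) in the libraries of the 4 groups, coloured by diagnosis; each point is a library. The pooled Pearson r was -0.52, and FSGS library 58 stands apart with a proximal tubule score of 1.25.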

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

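The alternatives that left out muscle-rich, least similar or single libraries were chosen only after the results were seen, and the others beforehand. Of 132 named gene calls, RLE scaling ended 2, the podocyte covariate 2, the library size covariate 19, the nephron segment covariate 31, and leaving out the 20 smallest libraries 46. The rank test weakened 58 and reversed 3, and limma-voom weakened 66 and reversed 3. Leaving out the library in which the gene was highest weakened 50 and reversed 2. Of 28 list calls 0 changed direction in any setting. All stayed past the threshold with RLE scaling, a prior count of 0.5 and without the 5 least similar libraries. That number was 27 with z-scores and without the muscle-rich libraries, 25 with the median and 16 without the 20 smallest libraries. With camera 0 stayed past it, so no list call held against the other genes. No paired analysis was possible because the numbers of the libraries only follow their order in the listing. The labels gave no clinical data, so treatment, kidney function and age could not be separated from diagnosis. Library size did not differ detectably between groups. Where a value moved, the cause was not tested unless fewer genes or libraries are named.

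Counts of genes that differed moved by more than 1.5 times as follows. With no low-count filter (more genes tested) they were 131 for MN vs MCD, 727 for FSGS vs MN, 144 for Other NS vs FSGS, 194 for Other NS vs MN and 1934 across the groups. The stricter filter (fewer genes) gave 0 for MN vs MCD, 3 for Other NS vs FSGS and 9 for Other NS vs MN. DESeq2 gave 54 for MN vs MCD and 0 for Other NS vs FSGS. With limma-voom they were 0 for MN vs MCD, 11 for FSGS vs MN, 1 for Other NS vs FSGS, 0 for Other NS vs MN and 665 across the groups. The rank test gave 844 for FSGS vs MCD, 0 for MN vs MCD, 21 for FSGS vs MN, 0 for Other NS vs FSGS and 25 for Other NS vs MN. The compared groups alone gave 3 for MN vs MCD, 3 for Other NS vs FSGS and 63 for Other NS vs MN. With the library size covariate the counts were 1 for MN vs MCD and 25 for Other NS vs MN. The nephron segment covariate gave 883 for FSGS vs MCD, 41 for FSGS vs MN, 21 for Other NS vs MN and 651 across the groups. Without the 20 smallest libraries they were 9 for MN vs MCD, 79 for FSGS vs MN, 511 for Other NS vs MCD, 7 for Other NS vs MN and 676 across the groups. Without the muscle-rich libraries they were 8 for MN vs MCD, 2 for Other NS vs FSGS and 6 for Other NS vs MN. Without the 5 least similar libraries they were 106 for FSGS vs MN and 134 for Other NS vs MN.

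Leaving out 1 of 53 libraries at a time gave 1296 to 1911 genes for FSGS vs MCD, 5 to 20 for MN vs MCD, 117 to 698 for FSGS vs MN, 624 to 1134 for Other NS vs MCD, 4 to 17 for Other NS vs FSGS, 11 to 86 for Other NS vs MN and 1016 to 1422 across the groups. FSGS library 24 gave the lowest and MN library 14 the highest count for FSGS vs MN (main value 406). Other counts that moved by more than 1.5 times were 235 for FSGS vs MN without FSGS library 3, 7 for MN vs MCD without MCD library 24, 8 for Other NS vs FSGS without Other NS library 26, and 12 and 27 for Other NS vs MN without Other NS libraries 17 and 26.

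The number of gene lists past the threshold was 0 with camera in all pairs. With the median it was 1 for MN vs MCD. Without the 20 smallest libraries it was 0 for MN vs MCD, 0 for FSGS vs MN and 1 for Other NS vs MN, and without the 5 least similar libraries 8 for Other NS vs MN. The share of variance explained and the correlations kept their counts of passing results to within 1.5 times.

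Values that changed direction came from genes carried by a few libraries. CRP, Other NS vs MCD, was -0.588 with DESeq2, -0.545 with limma-voom, -0.252 by rank and -1.26 without Other NS library 18, and CRP, Other NS vs FSGS, was -1.81, -0.908, -0.483 and -2.62 in the same order. PYGM, Other NS vs FSGS, was -0.508 with limma-voom, -0.197 by rank and -0.427 without the muscle-rich libraries. Without those libraries CKM, Other NS vs MCD, was -1.79 and CKM, Other NS vs FSGS, -0.749. There, TNNC2, Other NS vs MCD, was -0.254, TNNC2, Other NS vs FSGS, -0.0486 and TNNC2, Other NS vs MN, -0.00684. The muscle-rich libraries were picked by their level of muscle genes, so lower values of such genes were built into that setting.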

Other observations

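The tests of the immune, muscle and uncounted-gene patterns, the test of other LXR targets and the enlarged sets of splits, which for each comparison followed a smaller draw, were chosen only after results were seen, while the low-expression test and the covariate test of LXR targets were chosen before.

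Some libraries stood far from the others in their cell mixture. FSGS library 24 had the highest T and NK cell score (6.08, next 4.53), the highest B and plasma cell score (4.31) and macrophage score (6.82) and the lowest fatty acid oxidation score (5.95) of the libraries compared. FSGS library 58 had a proximal tubule score of 1.25, against 4.16 in the next lowest library and a median of 9.70, together with the highest principal cell score (7.58, median 5.64) and the lowest metallothionein score (1.86). MN library 14 held the highest tubular injury (8.33) and extracellular matrix (5.63) scores, and Other NS library 17 the highest complement score (6.39). MCD library 4 had a metallothionein score of 11.03, next to 9.07 in the second highest library. The library of unspecified diagnosis, with 32.7 M counts (M is 1e6), scored above 193 of the libraries compared for extracellular matrix (5.13, median 3.33), 192 for complement, 188 for TNF and NF-kB targets and 179 for T and NK cells, and above only 6 for nuclear oxidative phosphorylation and for mitochondrially encoded mRNAs.

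ABCG1, SREBF1 and SCD, which were lower in FSGS than in MN, are known targets of LXR, a nuclear receptor that senses sterols. A candidate explanation, formed from these data, is lower LXR activity in FSGS, and 12 further targets were scored to test it. Their score was -0.349 log2 in FSGS minus MN (SE 0.0554, 95% interval -0.458 to -0.241). The permutation p was 1e-05, the smallest the permutations can give. Of 10000 random lists of similar expression 0 reached as low (lowest -0.259). Such lists do not keep any correlation between the targets, so their spread can be too narrow. No conclusion is drawn from that count. Of the 12, only the cholesterol transporter ABCA1 passed over all genes (-0.41, adjusted p = 0.000707), and APOC1 was positive (0.11). Less proximal tubule and more injury in FSGS would leave no difference once both scores are covariates, but it was -0.313 (SE 0.0555) with them, so they argue against that as the whole cause. The same score was -0.205 in FSGS minus MCD (adjusted p = 0.0142), 0.269 in Other NS minus FSGS (0.00108), 0.144 in MN minus MCD (0.0531), 0.0638 in Other NS minus MCD (0.466) and -0.0803 in Other NS minus MN (0.271). Treatment and blood lipids, which the labels did not give, stay open as causes.

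Immune cell lists were higher in FSGS than in MCD. Against the other genes, none of T and NK cells, B and plasma cells, and macrophages passed camera with an estimated correlation (adjusted p = 0.245, 0.369 and 0.245). If less tubule in the FSGS tissue raised other cell types alike, T and NK cell genes would rise as much as endothelial genes. They rose by 1.28 log2 more (SE 0.291, permutation p = 5e-05). Both list differences had been seen before this test, and whether endothelium keeps its share as tubule is lost was not tested. No conclusion about less tubule is drawn from it. The part of the nephron sampled left a difference of 1.31 (SE 0.279) as a covariate, against 1.44 without it, and a few very high libraries do not carry it alone, since the medians differed by 1.19 (0.803 against -0.383, permutation p = 0.00235). More immune cells in the FSGS tissue may be the source, as a hypothesis found and tested on the same libraries. Less tubule in the FSGS tissue stays open, and so does treatment before biopsy, which was not given in the labels.

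Skeletal muscle genes topped the folds of Other NS. Of 12 muscle genes that were tested and named in no comparison, 8 were highest in Other NS library 5, the library that was highest for those named, and its 25 listed muscle genes summed to 2606 CPM against a median of 15.1 in all libraries and 14.7 in Other NS. A shift of the whole group is argued against by the difference of group medians over the 16 tested muscle genes, -0.0188 log2 against MCD. Muscle along the needle track is therefore a candidate source in a few biopsies, and no biological explanation was tested.

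Genes at 0 in every library were mostly genes that overlap another gene. Of 1893 such genes matched to the annotation, 85.6% had over 90% of their exon bases inside another gene's body, against 4.1% of 17037 genes with counts. Low expression in the tissue does not account for them, since 13.7% of the 1893 least counted genes lay inside another gene. All 32 members of the fixed lists at 0 lay inside another gene, and 69.8% of all nested genes were at 0. A candidate explanation is that reads over whole gene bodies were counted and those in overlaps were dropped, so that TIMP1, CD68, CCL5, CXCL10 and other such genes cannot be read as unexpressed.

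For each count of differing genes, 100 splits of the same libraries into groups of the same sizes were made, the real one included. For FSGS vs MCD 2 splits gave at least the 1534 genes of the real one (highest other 1931). A first draw of 40 splits had also held 2 such splits and had not excluded chance for that pair. The number was then raised for all pairs with the first draw kept, so the 100 splits do not exclude it either. Without adjustment over the comparisons, the splits argue against chance for Other NS vs MCD (1 split, 887 genes, highest other 35). The same held across the groups (1 split, 1198 genes, highest other 564). For Other NS vs MN (2 splits, 41 genes, highest other 93) a shuffled split called more genes than the real one. Chance cannot be excluded for MN vs MCD (5 splits, 14 genes, highest other 40), for FSGS vs MN (5 splits, 406 genes, highest other 1527) or for Other NS vs FSGS (17 splits, 16 genes, highest other 582). In the last 2 of these pairs the highest other split called several times the real number, although the median of the other splits was 3 and 5 genes. Such splits point to a structure of the samples, which was not tested further and can rest on few libraries, since FSGS vs MN had 117 genes without FSGS library 24 and 698 without MN library 14.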
